A study of Homo sapiens with 12 samples.

How the data were processed

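Gene expression was measured in total RNA from LNCaP, DU 145, RWPE-1 and PrEC cultures, with 3 biological replicate sets of each, on Illumina bead arrays with Cy3 label. The labels put each array in 1 of 4 cell types and give it a replicate number. Whether the PrEC sets came from different donors is not given in the sources used here. The methylation sequencing that the series mentions was not analysed here.

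Per the file headers, the deposited table of non-normalized values holds the signal intensity of each probe on each array and a detection p-value for it, without background subtraction. The submitters' processing notes name GenomeStudio 2009.1. A second deposited table holds intensity values that the authors had normalized. These have the same maximum on every array, near-equal medians of 94.28 to 94.43 and the same ranks as the signals. Quantile normalization can give such values, but the method is not given in the sources used here. One detection p-value column carries no array name and was assigned by elimination to PrEC replicate 1, the array otherwise without one.

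Signals were background corrected by normexp with parameters taken from the detection p-values, with an offset of 16, quantile normalized and put on the log2 scale, as in the neqc method of limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8). Of 24526 probes, 21834 carried the symbol of a gene (16922 genes) and 2692 carried none. Probes with a detection p under 0.01 on at least 3 of the 12 arrays were kept, 12525 in all, of which 11423 were named. Each gene was represented by its brightest kept probe, which left 9723 genes. Mean signal over background was 6.46 to 8.05 on 11 arrays and 3.60 on RWPE-1 replicate 2. The median SD of a gene over replicates was 0.19 in PrEC, 0.15 in RWPE-1, 0.16 in DU 145 and 0.09 in LNCaP, on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

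A limma model with 4 group means was fitted to all 12 arrays, and the 6 pairwise comparisons were tested with moderated statistics, adjusted by Benjamini-Hochberg over the genes of each comparison. A gene was called at an adjusted p under 0.05, two-sided, and counts at a change of at least 2-fold are given too. A fold is called "at least" where no probe of the gene was above background on any array of 1 group. It was then computed against the higher of the lowest signal among detected probes on an array and the value of the probe that represents the gene. On simulated data with a single log2 SD of 0.18 for every gene, the fit recovered 5 of 66 changes of 0.5 on the log2 scale. It recovered 55 of 67 changes of 1 and 60 of 66 changes of 2. There were 7 false calls among 9523 unchanged genes and none in a comparison without changes. Few genes were changed there, while 55.6% to 73.2% of genes were called in the 6 comparisons. The adjusted threshold is less strict when more genes change, so these counts do not give the recovery or false calls of those comparisons.

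Before the data were examined, 25 gene lists with 442 members were fixed, of which 302 members were tested. They cover cholesterol efflux and LXR targets, cholesterol biosynthesis, cholesterol uptake with SREBP control and storage, and fatty acid synthesis. They also cover the androgen receptor and its targets, markers of luminal, basal, mesenchymal, fibroblast, blood and neuroendocrine cells, squamous differentiation, proliferation, p53 targets and CDK inhibitors. The rest cover interferon, inflammation, MHC class I, genes methylated or raised in prostate cancer, DNA methylation machinery, cancer-testis antigens, the unfolded protein response, hypoxia, and integrins with proteases.

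Each list was tested with camera, the limma test of whether a list shifts relative to all other genes, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 25 lists of a comparison. Of 150 list tests, 58 passed at the preset correlation and 15 of these also passed with a correlation estimated from the data. Members were also adjusted over the list alone, which gave the same number of calls in 135 of the 150 cases and differed by at most 2 in the others. Test, median and mean of a list differed in sign in 16 cases, none of which passed.

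The genes named follow a rule fixed together with the lists: ABCA1, the 5 largest rises and 5 largest falls of a comparison by fitted log2 fold change among called genes of at least 2-fold whose arrays do not overlap and that are above background on every array of the higher group, and up to 4 called members of a list, with any member of the cholesterol lists. In RWPE-1 against PrEC, 1 of the 5 largest falls is left unnamed because its expression follows a common inherited deletion. Fitted values of genes at background in 1 group rest on the offset, so ranks by bounds can differ. Other probes of a gene can give another size of change. XIST and Y-linked genes were left out. The interferon ligands and the chromosomes named in the closing text were chosen after their values were seen.

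Counts of genes, list tests, counts of members in some lists and the named genes were recomputed with other choices: normexp without control probes, no background correction, median scaling, the authors' normalized values, no filter or a stricter filter on dim probes, the mean over the probes of a gene, a robust prior with an intensity trend, only the 2 groups compared, replicate number as a block, each array or replicate number left out in turn, and array quality weights. The last was added after seeing the data. Lists with fewer than 3 tested members under a choice have no value there, and chromosome shifts and the covariance were not recomputed. Across 18 pairs of groups and replicate numbers, arrays with the same number correlated at -0.126 to 0.237 after group means were removed, with a mean of 0.0438, and 6 of 12 arrays were closest to arrays of their own number, so replicates were not paired in the model. The mean over the genes of a chromosome was compared with that of all autosomal genes, its own included, by a permutation test with 100000 resamples. Chromosomes were taken from the GRCh38.p14 gene table. The covariance of the LNCaP and DU 145 comparisons was set against 20 simulations of unchanged groups.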

Results

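Total RNA from 4 kinds of cultured human prostate epithelial cells was measured on Illumina bead arrays, with 3 biological replicate sets of each and 12 arrays in all. PrEC are normal prostate epithelial cells. RWPE-1 is a line of normal prostate epithelial cells transformed with human papillomavirus. DU 145 and LNCaP are prostate carcinoma lines, of which LNCaP is the one known to respond to androgen. Mean signal per array was 461 to 663 on 11 arrays and 223 on RWPE-1 replicate 2, and 9807 to 11368 of the 24526 probes were above background on an array. Across the 9723 genes tested, which are not independent replicates, arrays of the same cell type correlated at 0.979 to 0.997. Mean correlation between cell types was lowest for LNCaP and PrEC (0.702) and highest for RWPE-1 and PrEC (0.897). The first principal component, with 53.4% of the variance, set LNCaP apart from the other cells, and the second, with 28.7%, set DU 145 apart. With 3 arrays per group, the number of arrays limits the precision of every value below. Standard errors (SE) are on the log2 scale, belong to the fitted change and pool the spread of the 4 cell types. Beside an "at least" fold they do not give the precision of that bound.

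The series title concerns loss of ABCA1, the membrane transporter that passes cholesterol and phospholipid from cells to apolipoproteins. ABCA1 was above background on all PrEC and RWPE-1 arrays. It stood in PrEC at a normalized log2 signal of 9.08 ± 0.34 (SD, n = 3) and in RWPE-1 at 9.25 ± 0.41 (SD, n = 3). It was lower in DU 145, at 8.02 ± 0.26 (SD, n = 3), and was not above background on any LNCaP array, where it read 4.63 ± 0.017 (SD, n = 3) with detection p of 0.361 to 0.407. LNCaP had at least 7.23-fold less ABCA1 than PrEC (log2 fold change -4.45, SE 0.20, limma adjusted p = 4.08e-11), at least 8.11-fold less than RWPE-1 (limma adjusted p = 2.76e-11) and at least 3.47-fold less than DU 145 (limma adjusted p = 1.18e-09). DU 145 had 2.08-fold less than PrEC (log2 fold change -1.06, SE 0.20, limma adjusted p = 0.000365) and 2.34-fold less than RWPE-1 (log2 fold change -1.23, SE 0.20, limma adjusted p = 9.14e-05). Every DU 145 array, up to 8.32, lay below every PrEC and RWPE-1 array, from 8.80. The difference between RWPE-1 and PrEC did not pass the test (log2 fold change 0.17, SE 0.20, limma adjusted p = 0.514). These SE and tests pool the spread of the 4 cell types. The small SD of LNCaP at background therefore also enters the comparisons without LNCaP. Both calls of DU 145 held with only the 2 groups compared in the fit. The array carried 1 probe for ABCA1, so no second probe could be read beside it.

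**Figure D1:**
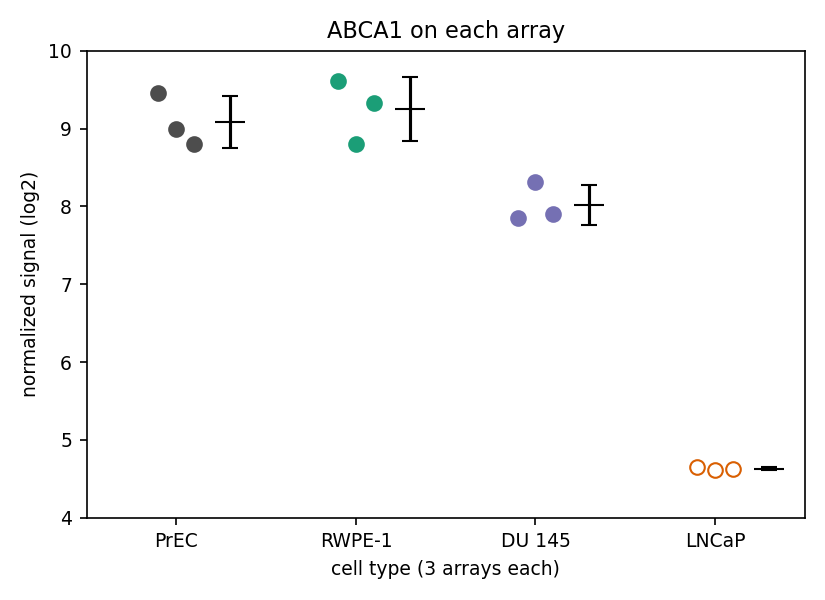
Normalized log2 signal of ABCA1 on each of 12 arrays (vertical axis) by cell type (horizontal axis); points are arrays, open where the probe was not above background, and bars are the mean and SD of 3 arrays. The 3 LNCaP arrays lie near 4.63 and are all at background, and the 3 DU 145 arrays lie below the PrEC and RWPE-1 arrays.

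LNCaP was compared with PrEC to ask how this carcinoma line differs from normal epithelium in culture, first in the genes that handle cholesterol. Cholesterol synthesis genes were lower in LNCaP: 2 of 15 tested were higher and 13 lower (15 called when adjusted over the list alone). Among them were MSMO1, a sterol methyl oxidase (6.74-fold, SE 0.15), SQLE, squalene epoxidase (6.08-fold, SE 0.18), MVD, mevalonate diphosphate decarboxylase (5.92-fold, SE 0.24), and HMGCS1, which makes HMG-CoA (5.76-fold, SE 0.17). The exceptions were TM7SF2, a sterol reductase (4.77-fold higher, SE 0.16), and PMVK, phosphomevalonate kinase (2.87-fold higher, SE 0.20). For sterol synthesis genes camera gave adjusted p = 0.00359, a call lost at adjusted p = 0.385 with an estimated correlation. Of the genes of cholesterol efflux and LXR targets, 3 of 13 tested were higher and 7 lower (10 called when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.112). PLTP, a phospholipid transfer protein, and APOE, an apolipoprotein, were at least 25.5-fold and at least 5.54-fold lower, and the lysosomal cholesterol carriers NPC2 and NPC1 were 3.95-fold and 2.17-fold lower. MYLIP, a ubiquitin ligase, was at least 8.20-fold higher, and NR1H3, the gene of LXR alpha, was 2.12-fold higher. The 3 probes of ABCG1, a transporter related to ABCA1, did not point one way: log2 fold change was -1.02 at the brightest and 1.09 and 0.49 at the others. Of the genes of cholesterol uptake, SREBP control and storage, 1 of 10 tested were higher and 7 lower (8 called when adjusted over the list alone). They included NCEH1, a cholesteryl ester hydrolase (5.36-fold lower, SE 0.18), VLDLR, a lipoprotein receptor (5.01-fold lower, SE 0.17), and INSIG1, which retains SREBP in the endoplasmic reticulum (3.64-fold lower, SE 0.26). In camera the shift had adjusted p = 0.0358, which was lost at adjusted p = 0.530 with an estimated correlation. This call was also lost without PrEC replicate 1 (adjusted p = 0.0777), without LNCaP replicate 1 (adjusted p = 0.0501) and without LNCaP replicate 3 (adjusted p = 0.0509), and over all alternatives adjusted p was 0.00592 to 0.530.

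Beyond cholesterol, the androgen receptor and its targets were higher in LNCaP: 12 of 14 tested were higher and 1 lower (13 called when adjusted over the list alone). KLK4, a kallikrein protease, was at least 86.1-fold higher (log2 SE 0.12), TMPRSS2, a surface protease, at least 76.4-fold higher (log2 SE 0.12), ACP3, prostatic acid phosphatase, at least 12.6-fold higher and KLK3, the gene of PSA, at least 7.12-fold higher. For androgen receptor targets camera gave adjusted p = 5.12e-06, and adjusted p = 0.00974 with an estimated correlation. All 14 were above background in LNCaP and 6 in PrEC, so the filter favoured a rise; with only probes above background on all 12 arrays 3 were called higher and the list call was lost (adjusted p = 0.253, and 2.49e-08 to 0.253 over all alternatives). Without any 1 of the LNCaP arrays 8 members were tested and 6 called higher, since genes above background in LNCaP alone then miss the filter of 3 arrays. Genes raised in prostate cancer went the same way, with 9 higher and 2 lower of 12 tested (11 when adjusted over the list alone), among them FOLH1, the gene of PSMA (at least 36.3-fold higher), and HPN, a surface protease (at least 17.1-fold higher), while ETV5, a transcription factor, was at least 12.5-fold lower. Camera gave adjusted p = 0.0227, and the call was lost at adjusted p = 0.170 with an estimated correlation. Without any 1 of the LNCaP arrays this call was lost (adjusted p 0.545 to 0.613, and 0.00918 to 0.613 over all alternatives), and the median log2 fold change of 1.79 became 0.80 to 0.86, with 8 of the 12 members tested. Of 22 cancer-testis antigens, the 7 tested were called higher (7 when adjusted over the list alone), but all 7 were above background in LNCaP and 0 in PrEC, so the filter itself favoured a rise. Without any 1 of the LNCaP arrays 1 member was tested, and with no filter the fitted median log2 fold change of 2.95, or 1.90 with members at their bounds, became 0.10. MAGEA6 was at least 20.6-fold and MAGEA12 at least 13.7-fold higher. Of basal epithelial markers, 0 of 14 tested were higher and 14 lower (14 called when adjusted over the list alone), including the basal keratins KRT14 (at least 296-fold) and KRT5 (at least 194-fold) and CAV1, a coat protein of caveolae (at least 198-fold). For basal markers camera gave adjusted p = 3.05e-11, and adjusted p = 0.0195 with an estimated correlation. Mesenchymal markers were lower too, with 1 higher and 10 lower of 11 tested (11 when adjusted over the list alone), among them TGFBI (at least 57.6-fold) and VIM, the gene of vimentin (54.5-fold). As a list it passed in camera (adjusted p = 2.63e-05; adjusted p = 0.0195 with an estimated correlation). Genes known to be methylated in prostate cancer were mostly lower, with 2 higher and 12 lower of 15 tested (15 when adjusted over the list alone), and GSTP1, a glutathione transferase, was at least 145-fold lower. The count higher was 0 to 3 when a PrEC array was left out and 1 to 3 for other arrays. The count lower was at least 12 under every alternative that gave a value. With only probes above background on all 12 arrays the list gave none, since 2 of the 15 were above background in LNCaP. For the methylated genes camera gave adjusted p = 1.05e-07, and adjusted p = 0.00953 with an estimated correlation. The filter favoured a fall in these 3 lists. Above background in PrEC and in LNCaP were 14 and 2 basal, 9 and 2 mesenchymal and 14 and 2 methylated genes.

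Immune and matrix genes were lower in LNCaP than in PrEC as well. Of inflammatory cytokines and NF-kB targets, 0 of 10 tested were higher and 8 lower (8 called when adjusted over the list alone), led by PTGS2, a prostaglandin synthase (at least 36.2-fold), and the cytokines IL1A (at least 31.4-fold) and IL1B (at least 21.6-fold). The list passed in camera (adjusted p = 0.000360) and also with an estimated correlation (adjusted p = 0.0244). Above background were 8 members in PrEC and 1 in LNCaP, so the filter favoured a fall. It did so too for squamous genes (12 and 2) and for integrins and proteases (21 and 7). In MHC class I presentation, 1 of 10 tested were higher and 9 lower (10 called when adjusted over the list alone), with the proteasome subunit PSMB8 at least 7.04-fold and HLA-E, whose probe can share signal with other HLA genes, 10.1-fold lower. For MHC class I genes camera gave adjusted p = 0.00131, a call lost at adjusted p = 0.138 with an estimated correlation. Interferon response genes stood at 1 higher and 11 lower of 20 tested (12 when adjusted over the list alone), and ISG15, a ubiquitin-like protein, was the member called higher (6.23-fold). Camera gave adjusted p = 0.0195, and the call was lost at adjusted p = 0.584 with an estimated correlation. In squamous differentiation, 1 of 15 tested were higher and 11 lower (12 called when adjusted over the list alone), with KRT13 at least 24.3-fold and S100A9 at least 22.9-fold lower. For squamous genes camera gave adjusted p = 0.000280, a call lost at adjusted p = 0.132 with an estimated correlation. Integrins and extracellular proteases gave 1 higher and 19 lower of 21 tested (20 when adjusted over the list alone), among them PLAU, the urokinase gene (at least 96.1-fold), and TIMP1, a protease inhibitor (at least 83.3-fold). By camera the list had adjusted p = 6.52e-10, and adjusted p = 0.132 with an estimated correlation, where the call was lost. In hypoxia and glycolysis, 2 of 13 tested were higher and 10 lower (12 called when adjusted over the list alone), with SLC2A1, a glucose transporter, 5.57-fold and ADM, adrenomedullin, at least 32.7-fold lower. For hypoxia genes camera gave adjusted p = 0.0204, a call lost at adjusted p = 0.132 with an estimated correlation.

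Over all genes, 7059 of 9723 differed between LNCaP and PrEC, 3930 higher and 3129 lower in LNCaP, and 3426 of these by at least 2-fold (1683 higher, 1743 lower). The arrays of the 2 groups did not overlap for 78.1% of genes, against 10% by chance. Ranked by fitted log2 fold change under the rule for named genes, which bounds can order otherwise, the largest rises were GAGE4, a cancer-testis antigen (at least 231-fold), EEF1A2, a translation elongation factor (at least 192-fold), KLK4, TMPRSS2 and LRRC26 (at least 84.7-fold). By the same fitted values the largest falls were FGFBP1, a carrier of fibroblast growth factors (at least 367-fold), KRT14, CAV1, GJB2, the connexin 26 gene (at least 241-fold), and KRT5. Of the genes called, 160 were above background in neither group, and probes for GAGE4 and the MAGEA genes can share signal with near-identical family members.

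DU 145 was compared with PrEC for the same question in a carcinoma line without androgen response. Cholesterol synthesis genes were lower here as well: 2 of 15 tested were higher and 11 lower (13 called when adjusted over the list alone). MSMO1 was 6.22-fold (SE 0.15) lower, EBP, a sterol isomerase, 3.35-fold (SE 0.19) lower, SC5D, a sterol desaturase, 3.28-fold (SE 0.19) lower and MVD 3.26-fold (SE 0.24) lower, and again PMVK (1.85-fold) and TM7SF2 (1.57-fold) were higher, the latter not past the threshold without replicate 3 of every cell type (adjusted p = 0.0737, and 6.13e-05 to 0.0737 over all alternatives). In camera the shift had adjusted p = 0.00286, which was lost at adjusted p = 0.502 with an estimated correlation. Among genes of cholesterol efflux and LXR targets, 5 of 13 tested were higher and 8 lower (13 called when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.325). PLTP was at least 32.2-fold lower and APOE 1.83-fold lower, while MYLIP was at least 6.90-fold higher and NPC1 1.68-fold higher. For cholesterol uptake, SREBP control and storage, 1 of 10 tested were higher and 7 lower (8 called when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.112). SREBF1, the gene of SREBP-1, was 5.98-fold (SE 0.18) lower and INSIG1 4.45-fold (SE 0.26) lower, and NCEH1 was 4.29-fold (SE 0.18) higher. Without PrEC replicate 3 the uptake list passed the threshold (adjusted p = 0.0466, and 0.0466 to 0.597 over all alternatives).

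Basal and squamous genes were lower in DU 145 than in PrEC, and proliferation genes were higher. Of basal epithelial markers, 0 of 14 tested were higher and 14 lower (14 called when adjusted over the list alone), with KRT14 at least 374-fold, KRT5 at least 245-fold and DSG3, a desmosomal cadherin, at least 38.3-fold lower. For basal markers camera gave adjusted p = 3.86e-11, a call lost at adjusted p = 0.0645 with an estimated correlation. Squamous differentiation gave 1 higher and 10 lower of 15 tested (11 when adjusted over the list alone), with KRT13 at least 30.7-fold lower. Camera gave adjusted p = 0.000276, and the call was lost at adjusted p = 0.210 with an estimated correlation. Of cell proliferation genes, 14 of 21 tested were higher and 0 lower (15 called when adjusted over the list alone), led by TYMS, thymidylate synthase (3.77-fold, SE 0.14), BIRC5, the survivin gene (2.70-fold, SE 0.14), and AURKA, a mitotic kinase (2.57-fold, SE 0.11). For proliferation genes camera gave adjusted p = 0.00847, a call lost at adjusted p = 0.565 with an estimated correlation. Targets of p53 were lower, with 0 higher and 12 lower of 13 tested (12 when adjusted over the list alone), among them GDF15, a secreted stress factor (at least 6.25-fold), and CDKN1A, the p21 gene (3.89-fold). By camera the list had adjusted p = 0.000276, and adjusted p = 0.210 with an estimated correlation, where the call was lost. CDKN2A, the gene of the inhibitor p16, was 15.9-fold (SE 0.28) higher. Among genes known to be methylated in prostate cancer, 2 of 15 tested were higher and 10 lower (12 called when adjusted over the list alone), including CCND2, cyclin D2 (at least 124-fold lower), PTGS2 (at least 45.7-fold lower) and GSTP1 (6.11-fold lower). For the methylated genes camera gave adjusted p = 0.00105, a call lost at adjusted p = 0.0645 with an estimated correlation. The count higher was 1 to 4 when single arrays were left out. Integrins and extracellular proteases stood at 1 higher and 18 lower of 21 tested (19 when adjusted over the list alone), with the kallikreins KLK5 (at least 206-fold) and KLK10 (at least 16.5-fold) lower and the protease inhibitor TIMP2 45.6-fold higher at the brighter of its 2 probes (log2 fold changes 5.51 and 2.32). The shift in camera had adjusted p = 6.00e-08, which was lost at adjusted p = 0.265 with an estimated correlation. Above background in PrEC and in DU 145 were 14 and 7 basal, 12 and 3 squamous and 21 and 10 integrin and protease genes. The filter thus favoured a fall in these lists as well. In hypoxia and glycolysis, 2 of 13 tested were higher and 9 lower (11 called when adjusted over the list alone), with ALDOC, an aldolase, 9.84-fold lower. For hypoxia genes camera gave adjusted p = 0.0162, a call lost at adjusted p = 0.210 with an estimated correlation. The androgen receptor and its targets gave 2 higher and 4 lower of 14 tested (6 when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.664). Interferon response genes in DU 145 gave 7 higher and 6 lower of 20 tested (14 when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.916).

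In all, 6361 genes differed between DU 145 and PrEC, 3436 higher and 2925 lower, and 2648 of these by at least 2-fold (1242 higher, 1406 lower). Arrays did not overlap for 66.1% of genes, against 10% by chance. By fitted log2 fold change under the rule for named genes, the largest rises were EEF1A2 (at least 147-fold), LMO3, a LIM domain protein (at least 53.5-fold), COXFA4L3 (at least 71.0-fold), PNMA2 (at least 44.3-fold) and MUC1, a mucin (98.8-fold), and the largest falls were KRT14, KRT6C (at least 352-fold), KRT5, KLK5 and GJB2 (at least 304-fold). The probes of LMO3 and of COXFA4L3 shared a direction but differed in size, with log2 fold changes of 2.60 to 7.05 and 1.70 to 6.82, and the KRT6C probe can share signal with the near-identical KRT6A and KRT6B.

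RWPE-1 was compared with PrEC to set a transformed line of normal epithelium beside the primary culture. Interferon response genes were higher in RWPE-1: 19 of 20 tested were higher and 0 lower (19 called when adjusted over the list alone). IFI27 was at least 33.5-fold higher (log2 SE 0.33), IFIT1, a sensor of viral RNA, 47.0-fold (SE 0.16) higher, ISG15 25.1-fold (SE 0.36) higher and BST2, the gene of tetherin, 23.2-fold (SE 0.15) higher. Camera gave adjusted p = 8.77e-12, and the call was lost at adjusted p = 0.120 with an estimated correlation. Squamous differentiation genes were higher too, with 12 higher and 1 lower of 15 tested (14 when adjusted over the list alone): PI3, the elafin gene, was 147-fold (SE 0.14) higher, SBSN at least 23.8-fold higher, S100A7 at least 15.7-fold higher and SPRR1A, a cornified envelope precursor, 26.4-fold (SE 0.15) higher. For squamous genes camera gave adjusted p = 1.51e-07, a call lost at adjusted p = 0.106 with an estimated correlation. Without RWPE-1 replicate 2, and without RWPE-1 replicate 3, 8 members were called higher. Above background in RWPE-1 and in PrEC were 20 and 14 interferon and 14 and 12 squamous genes, so the filter favoured a rise. With genes not above background set at their bounds, the median log2 fold change was 2.73 for the interferon list and 3.03 for the squamous list, against 2.92 and 3.09 as fitted.

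Sterol genes were lower in RWPE-1 than in PrEC. In cholesterol biosynthesis, 0 of 15 tested were higher and 14 lower (14 called when adjusted over the list alone), led by HMGCS1 (14.8-fold, SE 0.17), MVD (7.01-fold, SE 0.24), MSMO1 (5.73-fold, SE 0.15) and DHCR7, the last enzyme of a route to cholesterol (5.31-fold, SE 0.21). By camera the list had adjusted p = 6.50e-08, and adjusted p = 0.120 with an estimated correlation, where the call was lost. Of the 15 members, 11 were lower in all 3 lines than in PrEC. For uptake, SREBP control and storage, 0 of 10 tested were higher and 9 lower (9 called when adjusted over the list alone), with INSIG1 10.1-fold (SE 0.26) and VLDLR 6.14-fold (SE 0.17) lower. For uptake and storage genes camera gave adjusted p = 0.00101, a call lost at adjusted p = 0.230 with an estimated correlation. Among efflux genes and LXR targets, 3 of 13 tested were higher and 7 lower (10 called when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.158); PLTP was 11.7-fold and APOE 4.88-fold lower, and MYLIP was at least 3.40-fold higher. Fatty acid synthesis genes gave 1 higher and 9 lower of 11 tested (10 when adjusted over the list alone), with FADS2, a desaturase, at least 6.90-fold and FASN, fatty acid synthase, 3.32-fold lower. In camera the shift had adjusted p = 0.00120, which was lost at adjusted p = 0.205 with an estimated correlation.

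**Figure D2:**
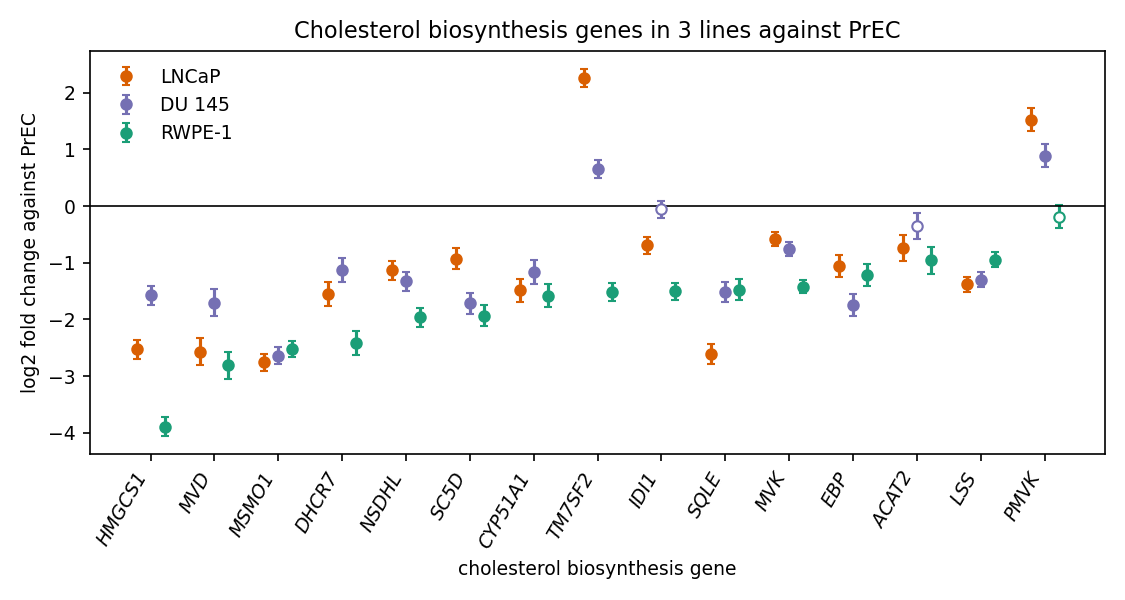
Log2 fold change against PrEC (vertical axis) of the 15 cholesterol biosynthesis genes tested (horizontal axis) in LNCaP, DU 145 and RWPE-1, 3 arrays per group; bars are SE, and open points did not pass the test. Most points lie below 0, and TM7SF2 and PMVK lie above 0 in LNCaP and DU 145.

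Several lists of other functions were lower in RWPE-1 than in PrEC. Basal epithelial markers gave 1 higher and 13 lower of 14 tested (14 when adjusted over the list alone), with KRT15 3.13-fold and LAMB3, a laminin chain, 5.09-fold lower. When single arrays were left out, the count higher was 0 in 2 fits each for PrEC, RWPE-1 and LNCaP arrays. For basal markers camera gave adjusted p = 7.49e-06, a call lost at adjusted p = 0.120 with an estimated correlation. Of luminal epithelial markers, 0 of 11 tested were higher and 8 lower (8 called when adjusted over the list alone), with KRT19 3.86-fold and FOXA1, a pioneer transcription factor, 2.53-fold lower. Camera gave adjusted p = 0.0104, and the call was lost at adjusted p = 0.184 with an estimated correlation. Integrins and extracellular proteases stood at 2 higher and 18 lower of 21 tested (20 when adjusted over the list alone), with MMP9, a gelatinase, at least 7.67-fold lower and TIMP2 15.4-fold higher at its brighter probe. For integrins and proteases camera gave adjusted p = 6.32e-07, a call lost at adjusted p = 0.196 with an estimated correlation. In hypoxia and glycolysis, 0 of 13 tested were higher and 11 lower (11 called when adjusted over the list alone), with PGK1, a glycolytic kinase, 3.21-fold lower. By camera the list had adjusted p = 0.000496, and adjusted p = 0.106 with an estimated correlation, where the call was lost. Among genes known to be methylated in prostate cancer, 2 of 15 tested were higher and 8 lower (10 called when adjusted over the list alone), with GPX3, a glutathione peroxidase, 7.42-fold lower. For the methylated genes camera gave adjusted p = 0.00521, a call lost at adjusted p = 0.106 with an estimated correlation. Markers of fibroblasts and smooth muscle, read as a check for other cells, gave 0 higher and 4 lower of 5 tested (4 when adjusted over the list alone). The shift in camera had adjusted p = 0.0394, which was lost at adjusted p = 0.184 with an estimated correlation. That call was also lost without any 1 of the PrEC arrays (adjusted p 0.0977 to 0.113) and without RWPE-1 replicate 2 (adjusted p = 0.0516), with 0.0244 to 0.368 over all alternatives. CDKN2A was 10.7-fold (SE 0.28) higher.

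Between RWPE-1 and PrEC 5403 genes differed, 2774 higher and 2629 lower, and 1659 of these by at least 2-fold (785 higher, 874 lower). Arrays did not overlap for 58.4% of genes, against 10% by chance. The largest rises by fitted value under the rule for named genes were PI3, HERC5, a ligase for ISG15 (112-fold), IFI27, IFIT1 and OASL (at least 27.1-fold), and the largest falls as fitted included PRAC1 (at least 29.9-fold), PCDH7, a protocadherin (at least 21.96-fold), FGFBP1 (30.4-fold) and TAGLN3 (at least 10.4-fold). RWPE-1 counts depended on the scaling: with arrays scaled to a common median instead of quantile normalized, the share of called genes that were higher went from 51.3% to 28.9% against PrEC, and the median log2 fold change of all genes from 0.03 to -0.18.

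**Figure D3:**
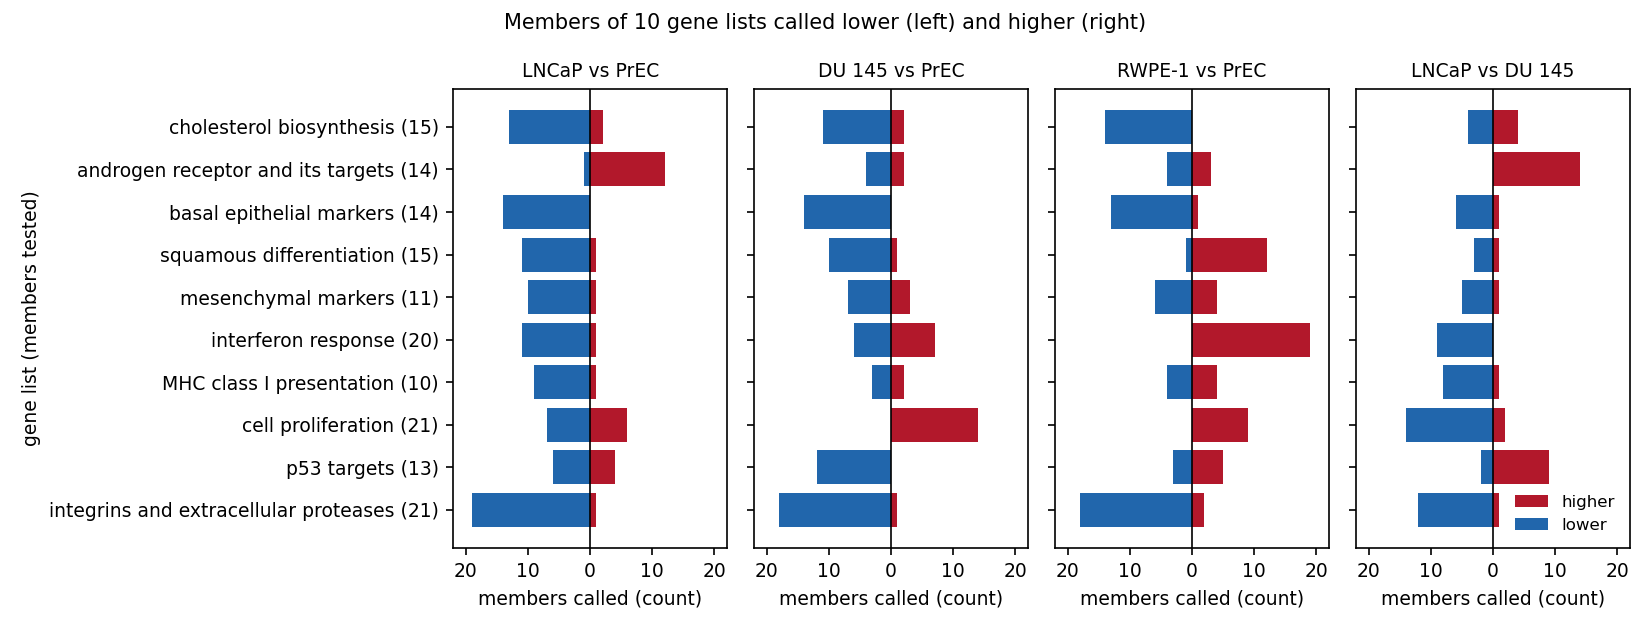
Number of members called lower (left of 0) and higher (right of 0) in 10 gene lists (vertical axis, with members tested) in 4 comparisons, 3 arrays per group. Androgen receptor targets are higher in LNCaP against PrEC (12 members) and DU 145 (14 members), and interferon response genes are higher in RWPE-1 against PrEC (19 members).

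The carcinoma lines were also compared with RWPE-1, the other culture of normal origin. The androgen receptor and its targets were again higher in LNCaP, with 12 higher and 1 lower of 14 tested (14 when adjusted over the list alone), and 6 called higher without any 1 of the LNCaP arrays. The call was lost with only probes above background on all 12 arrays (adjusted p = 0.135, and 1.13e-08 to 0.135 over all alternatives), where 3 were higher. KLK4 was at least 90.5-fold and STEAP2, a metalloreductase, at least 62.8-fold higher. For androgen receptor targets camera gave adjusted p = 1.51e-06, and adjusted p = 0.00797 with an estimated correlation. Interferon response genes were lower in LNCaP, 0 higher and 20 lower of 20 tested (20 when adjusted over the list alone), and in DU 145, 0 higher and 19 lower of 20 tested (19 when adjusted over the list alone), with IFI27 at least 25.7-fold and 37.3-fold lower. The interferon list had adjusted p = 3.04e-09 by camera in LNCaP and 5.73e-09 in DU 145, and both calls were lost with an estimated correlation (adjusted p = 0.137 and 0.291). Squamous differentiation genes were lower in LNCaP, 1 higher and 12 lower of 15 tested (13 when adjusted over the list alone), and in DU 145, 0 higher and 12 lower of 15 tested (13 when adjusted over the list alone), with PI3 at least 268-fold and at least 339-fold lower. For squamous genes camera gave adjusted p = 2.13e-07 in LNCaP and 5.73e-09 in DU 145, and with an estimated correlation adjusted p = 0.0430 in LNCaP and 0.141 in DU 145, where the call was lost. Above background in RWPE-1, LNCaP and DU 145 were 20, 10 and 13 interferon and 14, 2 and 3 squamous genes. The filter thus favoured a fall in both lines. For androgen receptor genes it favoured a rise in LNCaP, with 14 above background there and 6 in RWPE-1. For cholesterol synthesis genes in LNCaP, 8 of 15 tested were higher and 2 lower (10 called when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.149). In DU 145, 9 of 15 tested were higher and 2 lower (11 called when adjusted over the list alone), with 0 lower without RWPE-1 replicate 2 or 3 and 1 without any 1 of the DU 145 arrays, and the list did not pass in camera (adjusted p = 0.0899). The list passed in both lines without replicate 2 of every cell type (adjusted p = 0.0402 and 0.0208), and in DU 145 also without RWPE-1 replicate 2 alone (adjusted p = 0.0344), with a higher median than in RWPE-1 each time. Over all alternatives adjusted p was 0.0402 to 0.586 and 0.0208 to 0.722. HMGCS1 was 2.57-fold (SE 0.17) higher in LNCaP and 4.99-fold (SE 0.17) higher in DU 145. LNCaP and RWPE-1 differed in 7115 genes (3720 higher, 3395 lower in LNCaP), with no overlap of arrays for 80.1%, and DU 145 and RWPE-1 in 6577 (3397 higher, 3180 lower in DU 145), with no overlap for 69.8%, against 10% by chance. By at least 2-fold the counts were 3636 (1797 higher, 1839 lower) and 2904 (1432 higher, 1472 lower). Against RWPE-1, under median scaling, the share higher among called genes went from 52.3% to 67.7% for LNCaP and from 51.6% to 68.6% for DU 145, and the median log2 fold change from 0.06 to 0.40 and from 0.02 to 0.31. Against PrEC the LNCaP median went from 0.13 to 0.24.

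To ask what the carcinoma lines shared, genes were counted that went one way in both LNCaP and DU 145 against both PrEC and RWPE-1. There were 2287, 1161 higher and 1126 lower, and 703 of them by at least 2-fold in each comparison (241 higher, 462 lower). Genes were named by the smallest of the 4 fitted changes, which bounds can order otherwise. Among the rises were EEF1A2 and TFPI, an inhibitor of coagulation, which was at least 30.8-fold higher in LNCaP and at least 22.8-fold higher in DU 145 than in PrEC. SLAIN1 (at least 9.43-fold and at least 5.84-fold), SEPTIN3 (at least 12.4-fold and at least 5.61-fold) and DIPK1B (at least 8.44-fold and at least 7.72-fold) were higher in the same comparisons. By the same measure the shared falls were led by KRT14, KRT5, CCND2 (at least 98.4-fold and at least 124-fold), KLK5 (at least 163-fold and at least 206-fold) and IGFBP7, a secreted binding protein (at least 46.3-fold and at least 58.5-fold). The cell line is the unit for a statement on carcinoma, and with 2 lines on each side no test over lines was made. The other ways to pair the 4 cell types gave 1032 genes (LNCaP and RWPE-1 together) and 858 genes (DU 145 and RWPE-1 together).

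Against PrEC alone, LNCaP and DU 145 shared 1955 genes higher and 1805 lower, where independent lists of these sizes would share 1389 and 941, and 1107 genes went in opposite directions. Log2 fold changes of the 2 comparisons correlated at 0.511 across genes. The same PrEC arrays enter both, and simulated groups without any difference gave 0.4996, so the correlation itself tells little. The covariance was 1.03, against 0.015 in the simulations. Those hold only the spread of replicates, so any way in which PrEC itself differs from both lines also raises the covariance. Neither it nor the shared counts tell a change shared by the carcinoma lines from one particular to PrEC. The opposite count was 718 under median scaling and 679 without replicate 3.

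LNCaP and DU 145 were compared to ask how the carcinoma lines differ. The androgen receptor and its targets were higher in LNCaP, with 14 higher and 0 lower of 14 tested (14 when adjusted over the list alone), and 8 called higher without any 1 of the LNCaP arrays and 5 with only probes above background on all 12 arrays. KLK4 was at least 83.4-fold, TMPRSS2 at least 74.0-fold and SLC45A3, a sugar transporter, 29.9-fold (SE 0.20) higher. This held in camera at adjusted p = 4.40e-08 and at adjusted p = 0.00521 with an estimated correlation. Cancer-testis antigens gave 6 higher and 1 lower of 7 tested (7 when adjusted over the list alone), with MAGEA6 at least 19.9-fold higher, but 7 were above background in LNCaP and 1 in DU 145, so the filter favoured a rise here too, and with no filter the fitted median log2 fold change of 2.78, or 1.86 with members at their bounds, became 0.08. Genes known to be methylated in prostate cancer were lower in LNCaP, with 0 higher and 10 lower of 15 tested (10 when adjusted over the list alone), led by CAV1 (at least 111-fold) and ANXA2, an annexin (at least 286-fold). For the methylated genes camera gave adjusted p = 1.002e-05, and adjusted p = 0.0120 with an estimated correlation. Above background in LNCaP and in DU 145 were 14 and 6 androgen receptor and 2 and 11 methylated genes. The filter thus favoured a rise in the former list and a fall in the latter. In MHC class I presentation, 1 of 10 tested were higher and 8 lower (9 called when adjusted over the list alone), with PSMB8 at least 10.4-fold lower. By camera the list had adjusted p = 0.00769, and adjusted p = 0.365 with an estimated correlation, where the call was lost. Cell proliferation genes were lower in LNCaP, with 2 higher and 14 lower of 21 tested (16 when adjusted over the list alone), and TOP2A, a topoisomerase, was 3.87-fold (SE 0.12) lower. For proliferation genes camera gave adjusted p = 0.0183, a call lost at adjusted p = 0.640 with an estimated correlation. Integrins and extracellular proteases gave 1 higher and 12 lower of 21 tested (13 when adjusted over the list alone), with PLAU at least 124-fold lower. In camera the shift had adjusted p = 0.00769, which was lost at adjusted p = 0.625 with an estimated correlation. Inflammatory cytokines and NF-kB targets gave 0 higher and 5 lower of 10 tested (5 when adjusted over the list alone), with CXCL8, a neutrophil chemokine, at least 14.7-fold and IL6 at least 3.73-fold lower. For inflammatory genes camera gave adjusted p = 0.0298, a call lost at adjusted p = 0.230 with an estimated correlation. Without any 1 of the DU 145 arrays this call was lost (adjusted p 0.113 to 0.183, and 0.0110 to 0.230 over all alternatives), and the median log2 fold change of -1.12 became -0.22 to -0.12, with 8 of the 10 members tested.

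Between LNCaP and DU 145, cholesterol synthesis genes gave 4 higher and 4 lower of 15 tested (8 when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.830). Genes of cholesterol efflux and LXR targets stood at 3 higher and 8 lower of 13 tested (11 when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.226). APOE was at least 3.02-fold lower in LNCaP, NPC1 3.66-fold (SE 0.16) lower and NR1H3 4.04-fold (SE 0.13) higher. In uptake, SREBP control and storage, 2 of 10 tested were higher and 6 lower (8 called when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.676); NCEH1 was 23.0-fold (SE 0.18) lower and SREBF1 6.30-fold (SE 0.18) higher in LNCaP. Between the lines 6578 genes differed, 3416 higher and 3162 lower in LNCaP, and 3048 of these by at least 2-fold (1458 higher, 1590 lower), with no overlap of arrays for 75.4%, against 10% by chance. The largest rises by fitted value under the rule for named genes were GAGE4 (at least 224-fold), PRAC1 (at least 96.8-fold), KLK4, TMPRSS2 and LCP1, an actin bundling protein (at least 77.1-fold), and the largest falls as fitted were LGALS1, galectin 1 (at least 146-fold), CAV1, PLAU, ANXA2P1 (at least 123-fold) and MUC1 (at least 106-fold). By its bound ANXA2 fell further than these. The ANXA2P1 probe can share signal with ANXA2.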

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

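Of the tests in this part, the demand for at least 2-fold in each comparison of a gene and the reading of IFNL1, IFNE and IFNA8 were chosen only after the results were seen. Each result below, except the probes without a gene symbol, rose in one line and fell in another against the same PrEC arrays, and the difference between the lines passed its own test.

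The interferon response genes were higher in RWPE-1 than in PrEC (median log2 fold change 2.92) and lower in LNCaP (median -0.60), both calls lost with an estimated correlation (adjusted p = 0.120 and 0.584), and LNCaP lay below RWPE-1 (median -3.99, or -3.73 with undetected genes at their bounds, adjusted p = 3.04e-09, or 0.137 with an estimated correlation). The dim array RWPE-1 replicate 2 is argued against as the cause. Without it 16 of the 18 members then tested were called higher than in PrEC, against 19 of 20 with it. Expression of an interferon gene by RWPE-1 could raise these genes, but 0 of 21 probes for interferon ligands were above background on all 3 RWPE-1 arrays and higher than in PrEC. This leaves it open, since ligand mRNA can be too scarce to detect. IFNL1, named after its values were seen, read higher in RWPE-1 than in PrEC (limma adjusted p = 1.24e-08 over the 21 probes) but was above background on 1 of 3 RWPE-1 arrays and on none of the other 9, so no fold is given and it does not decide the matter. Other ligands went the other way. IFNE was above background on all 3 PrEC arrays but no RWPE-1 array, and read lower in RWPE-1 (limma adjusted p = 9.13e-06). IFNA8, above background on every array, was lower too (log2 fold change -0.36, limma adjusted p = 0.00485). The viral transformation of RWPE-1 and its culture medium stay open as well and were not tested.

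Squamous differentiation genes were higher in RWPE-1 than in PrEC and lower in both carcinoma lines, 3 calls lost with an estimated correlation (adjusted p = 0.106 for RWPE-1, 0.132 for LNCaP and 0.210 for DU 145). The medians of LNCaP and DU 145 against RWPE-1 were -6.19 (adjusted p = 2.13e-07) and -5.35 (adjusted p = 5.73e-09, or 0.141 with an estimated correlation). With undetected genes at their bounds the medians were -5.18 and -5.20. Differences of single genes are as fitted, and where a gene was not above background in 1 of the lines the bound is the smallest difference the signals support. The log2 change against PrEC in LNCaP minus that in DU 145 was -4.52 for NCEH1, -7.17 for VIM, -8.42 for MUC1 (bound -6.73) and -4.89 for CXCL8 (bound -3.87) with a largest limma adjusted p of 2.04e-11. For LNCaP minus DU 145 the difference was 7.05 for GDF15 (bound 6.14) and 7.80 for PRAC1 (bound 6.60) with a largest limma adjusted p of 8.33e-11. The log2 change against PrEC in LNCaP minus that in RWPE-1 was -7.16 for KRT13 (bound -5.66), -9.23 for S100A9 (bound -7.55), -8.61 for TGFBI (bound -6.92), -4.38 for MUC1 (bound -2.69), -9.75 for PI3 (bound -8.07) and -7.74 for SPRR1A (bound -6.22) with a largest limma adjusted p of 6.15e-11. For LNCaP minus RWPE-1 the difference was 3.78 for TM7SF2, 4.40 for FOXA1, 7.83 for PRAC1 (bound 6.72), 6.63 for STEAP2 (bound 5.97) and 5.52 for SLC45A3 with a largest limma adjusted p of 1.42e-11. The log2 change against PrEC in DU 145 minus that in RWPE-1 was -6.25 for GDF15 (bound -5.34), -7.30 for KRT13 (bound -6.001), -5.05 for S100A9, -2.96 for CDKN1A, -9.60 for PI3 (bound -8.41) and -7.80 for SPRR1A (bound -6.55) with a largest limma adjusted p of 1.60e-09. For DU 145 minus RWPE-1 the difference was 2.69 for FOXA1 and 4.66 for CXCL8 (bound 4.33) with a largest limma adjusted p of 3.64e-10. MUC1 was read at the brighter of its 2 probes, which gave -1.79 and -0.07 in LNCaP against PrEC. Of 1102 probes without a gene symbol that were above background, which the comparisons of genes do not use, 786 were called between LNCaP and PrEC.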

How the results depend on the processing

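Array quality weights were added as an alternative after the data were seen, and every other alternative was planned. ABCA1 kept its side of the threshold in all 6 comparisons under the 25 alternatives that kept its probe, with replicate number as a block included (the filter on all 12 arrays removes it), and its direction in the 5 it passed; RWPE-1 against PrEC, never past the threshold, ranged from -0.12 under median scaling to 0.39 without RWPE-1 replicate 2. Blocked counts of called genes were 7104, 6450, 5435, 7142, 6619 and 6603 in the order LNCaP, DU 145 and RWPE-1 against PrEC, LNCaP and DU 145 against RWPE-1, and LNCaP against DU 145; 2308 genes set both carcinoma lines apart, 3828 were shared by LNCaP and DU 145 against PrEC, and 1126 were opposite. Keeping only probes above background on all 12 arrays tests fewer genes, and the 6 counts were then 4557, 4056, 3559, 4578, 4244 and 4232, with 1344 for both carcinoma lines, 2374 shared and 630 opposite. With all probes of the main filter and a demand for at least 2-fold the counts were 3426, 2648, 1659, 3636, 2904 and 3048. The opposite count was 718 under median scaling, where the cause was not tested, and 679 to 1179 when arrays were left out, lowest without replicate 3.

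With an estimated correlation, the 5 calls of cholesterol lists against PrEC were lost, while the medians were unchanged. The estimated correlations were not kept, so the reason for the lost calls was not tested. The calls were cholesterol biosynthesis in LNCaP (-1.14, adjusted p = 0.385), DU 145 (-1.30, adjusted p = 0.502) and RWPE-1 (-1.52, adjusted p = 0.120), and uptake, SREBP control and storage in LNCaP (-0.78, adjusted p = 0.530) and RWPE-1 (-0.74, adjusted p = 0.230). Adjusted p over all alternatives was 0.000240 to 0.385, 0.000182 to 0.502, 6.00e-11 to 0.120, 0.00592 to 0.530 and 0.000114 to 0.230 in this order. When arrays were left out, the median of the uptake list was -0.92 to -0.69 in LNCaP (adjusted p 0.0125 to 0.0777; lost without PrEC replicate 1, LNCaP replicate 1 or LNCaP replicate 3) and -0.65 to -0.43 in DU 145 (adjusted p 0.0466 to 0.192; passed without PrEC replicate 3). Integrins and proteases in DU 145 against RWPE-1 had a median of -0.10 under the filter on all arrays, where the sign of the test turned (adjusted p = 0.962). ABCG1 turned with the mean over its probes, whose directions differ, to 0.19 in LNCaP, -0.13 in DU 145 and 0.90 in RWPE-1 against PrEC and to 0.32 in LNCaP against DU 145; the cause was not tested. Among the other list results, 83 lost and 62 gained a call, among single genes 23 lost (18 of them PLTP in LNCaP against DU 145) and 1 gained one, and 197 counts of list members moved by over 1.5 times. Signal over background limits dim genes most, and the low array RWPE-1 replicate 2 (3.60) is the weakest of the 12. Without an array, genes above background in its cell type alone miss the filter and have no value. A block for the chip was not run, since no chip is named.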

Other observations

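Of the tests in this part, those on ABCA1, on cholesterol synthesis genes, on the ways to pair the cell types and on chromosomes were chosen only after the results were seen. Several gene groups have not been described yet. Fatty acid synthesis genes in LNCaP gave 3 higher and 5 lower of 11 tested (8 when adjusted over the list alone) against PrEC, and in DU 145 1 higher and 6 lower of 11 tested (8 when adjusted over the list alone), with SCD, a desaturase, 3.05-fold (SE 0.17) and 2.86-fold (SE 0.17) lower, and neither list passed (adjusted p = 0.452 and 0.0662). The DU 145 list passed without DU 145 replicate 1 (adjusted p = 0.0391) and without PrEC replicate 3 (adjusted p = 0.0362), with 0.0250 to 0.565 over all alternatives. Luminal epithelial markers split in LNCaP, 4 higher and 3 lower of 11 tested (7 when adjusted over the list alone, camera adjusted p = 0.679), with HOXB13, a prostate homeobox factor, at least 13.6-fold higher and KRT19 169-fold (SE 0.13) lower. DU 145 had 6 higher and 4 lower of 11 tested (10 when adjusted over the list alone, camera adjusted p = 0.735), with CLDN3, a tight junction protein, at least 2.51-fold higher and CDH1, E-cadherin, 4.08-fold (SE 0.12) lower. Mesenchymal markers in DU 145 gave 3 higher and 7 lower of 11 tested (10 when adjusted over the list alone, camera adjusted p = 0.0662), and SPARC, a matrix protein, was at least 18.9-fold lower.

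Cell proliferation genes in LNCaP gave 6 higher and 7 lower of 21 tested (13 when adjusted over the list alone) against PrEC (adjusted p = 0.731) and p53 targets 4 higher and 6 lower of 13 tested (10 when adjusted over the list alone, camera adjusted p = 0.534), with GDF15 11.3-fold (SE 0.34) higher and SFN, a 14-3-3 protein, at least 64.2-fold lower. CDK inhibitors and the RB family gave 6 higher and 4 lower of 11 tested (10 when adjusted over the list alone) in LNCaP (adjusted p = 0.818) and 6 higher and 0 lower of 11 tested (6 when adjusted over the list alone) in RWPE-1 (adjusted p = 0.0567). In RWPE-1 the list passed without RWPE-1 replicate 1 (adjusted p = 0.0341), RWPE-1 replicate 3 (adjusted p = 0.0431) or LNCaP replicate 2 (adjusted p = 0.0497), with 0.009995 to 0.184 over all alternatives. Cell proliferation genes in RWPE-1 gave 9 higher and 0 lower of 21 tested against PrEC (9 when adjusted over the list alone, camera adjusted p = 0.0562). That list passed in some fits with 1 array left out (camera adjusted p 0.0198 to 0.0497). In DNA methylation machinery, LNCaP had 3 higher and 5 lower of 9 tested (8 when adjusted over the list alone, camera adjusted p = 0.534), with DNMT3B, a DNA methyltransferase, 1.38-fold (SE 0.15) higher, a call lost under median scaling and without replicate 3 of every cell type (adjusted p = 0.120 for the latter, and 0.000992 to 0.120 over all alternatives). The unfolded protein and amino acid stress response gave 3 higher and 3 lower of 14 tested (6 when adjusted over the list alone, camera adjusted p = 0.647), with HSPA5, an endoplasmic reticulum chaperone, 6.06-fold (SE 0.19) lower. Neuroendocrine markers gave 2 higher and 1 lower of 3 tested (3 when adjusted over the list alone, camera adjusted p = 0.647), with DDC, a decarboxylase, at least 19.4-fold higher. As checks for other cells, fibroblast and smooth muscle markers gave 2 higher and 3 lower of 5 tested (5 when adjusted over the list alone, camera adjusted p = 0.647) and blood and endothelial markers 1 higher and 3 lower of 4 tested (4 when adjusted over the list alone, camera adjusted p = 0.534), with VWF, von Willebrand factor, at least 5.05-fold higher.

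ABCA1 was at background in LNCaP. Weak LNCaP arrays are argued against, since their mean signal was 1.102 times that of the PrEC arrays. A general loss of LXR target expression could lower ABCA1. Of 7 other LXR targets 3 were called lower in LNCaP than in DU 145 (ABCG1 at its brightest probe, APOE and PLTP). LPCAT3 and SREBF1 were higher and MYLIP and SCD were not called, which leaves a part for it open. The call of ABCG1 turned with its probes: the others gave log2 fold changes of 1.65 and 0.83. The mean over its probes was 0.32 higher in LNCaP (limma adjusted p = 0.0258). PLTP was above background in neither line, and its call (limma adjusted p = 0.0489) was lost in 18 of 25 alternatives, with 0.01996 to 0.367 over them. A base difference under the ABCA1 probe could hide the transcript in LNCaP, and with 1 probe for the gene it cannot be told apart from a loss of expression. Methylation of the gene, a biological explanation, was not analysed here.

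Cholesterol synthesis genes were lower in LNCaP, DU 145 and RWPE-1 than in PrEC, list calls lost with an estimated correlation (adjusted p = 0.385, 0.502 and 0.120). Background correction or array scaling is argued against, since the median over the list was at most -0.953 under 4 other normalizations in the 3 comparisons. Dependence on one PrEC array is argued against too, since at least 11 of 15 members were called lower whichever PrEC array was left out. A difference in culture medium may act on these genes. Of 11 fatty acid synthesis genes, 3 were lower and 1 higher in all 3 lines, against 11 lower and 0 higher of 15 cholesterol synthesis genes. The medium goes with the cell type and cannot be told apart from it, whichever way these counts fall. The cell type itself stays open, and since the 3 comparisons share the PrEC arrays they are not independent of each other.

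Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. The real split gave 7059 genes for LNCaP and PrEC, 6361 for DU 145 and PrEC, 5403 for RWPE-1 and PrEC, 7115 for LNCaP and RWPE-1, 6577 for DU 145 and RWPE-1 and 6578 for LNCaP and DU 145. The highest count of any other split was 0 in limma in each comparison, with at most 186, 1091, 964, 139, 612 and 159 genes at an unadjusted p under 0.05. Each other split has both cell types on each side, so the difference between them widens the error of the fit. Counts near 0 follow from this, and they do not show whether the real counts arose by chance. The 3 ways to pair the 4 cell types are also too few, with 2287 genes for the carcinoma lines together and 1032 for the next.

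Genes of some chromosomes moved together. A shift is the mean log2 fold change of a chromosome minus that of all autosomal genes above background on all 6 arrays of a comparison. It passed at an adjusted p under 0.05 in 67 of 132 cases (permutation test, smallest possible p 1e-05). These were 4 in LNCaP, 12 in DU 145 and 13 in RWPE-1 against PrEC, 13 in LNCaP and 16 in DU 145 against RWPE-1, and 9 in LNCaP against DU 145. In RWPE-1 against PrEC, genes of chromosome 20 were shifted by 0.56, with 146 higher and 23 lower of 235, and genes of chromosome 9 by 0.48. Genes of chromosome 22 were shifted by -0.52, with 8 higher and 96 lower of 166, those of chromosome 18 by -0.47 and those of chromosome 3 by -0.43. Genes of a chromosome are not independent of each other, nor are the 132 cases, since the comparisons share groups. A shift in a single line enters several of them. Genes of chromosome 20, at 0.56 in RWPE-1 against PrEC, were shifted by -0.70 in LNCaP and -0.58 in DU 145 against RWPE-1. The mean replaced the median after a first run, and medians gave 66 of 132.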
